A study of Rattus norvegicus with 5 samples.

How the data were processed

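The series holds RNA sequencing of whole corneas from 5 male Sprague-Dawley rats aged 6 months. Per the labels, 3 corneas came from wild-type rats and 2 from transgenic P1 hMR rats, which carry the human gene NR3C2 for the mineralocorticoid receptor and express it in excess. Genotype is the only difference that the labels name. Per the labels' protocols, RNA was isolated with a column kit that includes a DNase step, and libraries followed standard Illumina protocols. Whether the libraries keep strand is not given in the sources used here, so reads of a gene and of an antisense partner cannot be told apart. Each column of the deposited tables matched the description of 1 sample. The protocol speaks of rats whose corneas were dissected, and the values are taken as 1 rat per library; no litter, day of dissection or time of day is given in the sources used here.

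The authors deposited 2 tables of estimated (expected) counts, 1 per gene and 1 per isoform, with a human NR3C2 feature beside the rat genes in both. Per the submitters' processing notes, FastQC, fastp, STAR 2.5.3a, RSEM 1.2.28, DESeq2 1.26.0 and edgeR 3.28.0 were used with the rat build rn6; the notes give no role or order for these tools. Fractional values in the files fit estimated counts of the kind RSEM makes, in which a read shared by several transcripts is divided among them. Values of near-identical copies, such as RT1 (rat major histocompatibility) genes, crystallins, keratins and haemoglobins, are therefore uncertain, and single isoforms more so than genes. Per the values as deposited, the expected counts are neither normalized nor log-transformed, since column totals differ between libraries. Gene-table totals were 27692181, 20874010 and 21920046 counts in wild-type corneas 1 to 3 and 26280687 and 30449675 in transgenic corneas 1 and 2. The gene table has 20339 genes, of which 4074 were at 0 in all 5 libraries; 16183 symbols matched a RefSeq table of assembly GRCr8 directly and 17043 with synonyms. That assembly was used for gene names and gene order, and no coordinates are given. The isoform table has 55002 isoforms, 26948 of them without a gene name, and 1430 gene names that the gene table lacks.

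Expected counts were rounded to whole numbers. Genes were kept by the default filterByExpr rule of edgeR (a minimum count of 10), normalized by TMM and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, robust, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Isoforms were tested in the same way. The standard error of a log2 fold change is its size divided by the square root of F. CPM is the library-size-scaled count of edgeR's cpm function after TMM; means are given ± SD over 3 wild-type and 2 transgenic corneas, and log2 fold changes ± SE are transgenic against wild-type. All adjusted p-values of genes and isoforms come from this edgeR test unless another tool is named. Binomial intervals of the human share and floors (3 counts) cover counting error only, since reads without molecular identifiers are not independent molecules. Intervals of score differences and slopes are t intervals of linear models over the libraries, so they rest on the spread between libraries.

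Before the data were examined, 25 gene lists were fixed for cell types of the cornea and its neighbours and for pathways, together with the design and the alternatives. Each list was compared with all other tested genes by camera in limma 3.58.1, with a preset inter-gene correlation of 0.01 and adjustment over the 25 lists; adjusted p-values of lists come from camera unless another tool is named. At the preset correlation the camera p-value takes genes as its units, so it does not measure the spread between rats. With an estimated correlation its degrees of freedom come from the libraries. Members were also adjusted over the list alone. A library's score for a list is the mean of log2(CPM + 0.5) of its members, as a deviation from the wild-type mean. The pigment score uses pigment-cell genes, and the clock score is the mean of output and repressor genes of the circadian clock minus that of the genes of the opposite phase.

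Genes are named by a rule fixed in advance: the receptor genes, then up to 12 called genes per direction with a mean of at least 1 CPM and no overlap between groups, then, as few were called, the 10 of smallest p among named genes that meet the same conditions, then the 2 tested members of smallest p in each list, and the 5 named isoforms of smallest p. Other genes are named as members of a list and were chosen after their values were seen. Some members of the lists, 1 of them chosen by the rule, are counted in their lists but not reported here by name.

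The procedure was tested on simulated counts with the means, library sizes and gene-wise spread of these libraries, for the comparison of transgenic with wild-type corneas over 13304 genes. Of 50 genes changed at each fold, it recovered 14 at 1.5-fold, 37 at 2-fold, 48 at 4-fold and 50 at 8-fold, with 22 unchanged genes called; with no gene changed it called 5. Over 27110 simulated isoforms it recovered 0, 4, 17 and 29 of 50 at the same folds, with 3 unchanged isoforms called. A list of 25 genes shifted by 0.4 on the log2 scale was found, and none of the unshifted lists was called. The simulated genes were drawn independently of each other, so false calls for lists with correlated members were not tried. In the real libraries the estimated correlation within a list was as high as 0.630, for the retina list.

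Alternatives were RLE size factors, no filter, a stricter filter (1 CPM in at least 3 samples), the replicate number as a block, each library left out in turn, DESeq2 1.42.0, limma voom, a minimum fold change of 1.5, and for lists an estimated correlation, fry and a ranking by the F statistic. Others were chosen after seeing the data: genes added from isoform sums, libraries thinned to the smallest total, and clock or pigment scores as covariates for the lists. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.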

Results

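Corneal transcripts were counted in 3 wild-type and 2 transgenic P1 hMR rats to ask how excess mineralocorticoid receptor (MR), a steroid receptor that binds aldosterone and glucocorticoids, alters gene expression in the cornea. Gene-table totals ran from 20874010 to 30449675 counts per library. Krt12, the keratin of the corneal epithelium, was the most abundant gene in every library, with 3.33% to 4.49% of counts, and mitochondrial genes took 3.65% to 4.46%. Pearson correlations of log2 CPM across genes, which are not independent replicates, lay between 0.982 and 0.984 within wild-type, at 0.985 within transgenic and between 0.974 and 0.985 across genotypes.

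Human NR3C2, the transgene, was read only in the transgenic corneas. Its counts were 0, 0 and 0 in the wild-type libraries and 1094 and 1146 in the transgenic ones, or 39.3 ± 4.03 CPM (SD, n = 2). The lower transgenic value was at least 248.5-fold higher than the highest wild-type floor of 3 counts per library, and the gene passed the edgeR test (adjusted p = 1.09e-05). Rat Nr3c2, the endogenous gene, gave 3.72 ± 0.722 CPM in wild-type and 5.24 ± 0.437 CPM in transgenic corneas, a ratio of 1.41; both transgenic values lay above all 3 wild-type values, but the difference did not pass (log2 fold change 0.49 ± 0.25, adjusted p = 0.820). The summed CPM of both genes, not scaled for transcript length, was 11.99-fold higher in transgenic corneas. Human reads made up 88.4% of MR counts in transgenic cornea 1 (95% exact binomial interval 86.5% to 90.1%) and 88.1% in cornea 2 (86.2% to 89.8%). Among 264 wild-type MR counts 0 were human, which allows a share of up to 1.14%. Human and rat MR sequences are related, so the split rests on the authors' allocation of reads.

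**Figure D1:**
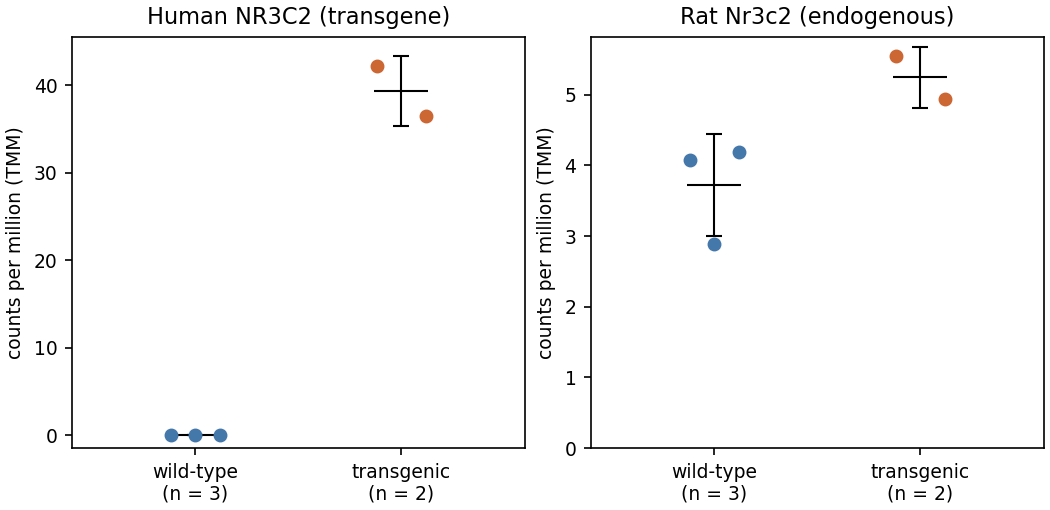
CPM (vertical axes, linear, with different scales) of human NR3C2 and rat Nr3c2 in 3 wild-type (blue) and 2 transgenic (orange) corneas; points are libraries, and bars are the mean ± SD. Human NR3C2 was 0 in every wild-type library and 42.2 and 36.5 CPM in the transgenic ones.

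Beyond the transgene, no gene passed the edgeR test. Of 13304 genes tested, 1 rose (NR3C2) and 0 fell; 841 had an unadjusted p under 0.05 (584 higher and 257 lower in transgenic corneas), against 665 by chance. That number rests on single libraries: it was 783, 566 or 1441 without wild-type cornea 1, 2 or 3 and 1114 or 458 without transgenic cornea 1 or 2. Both transgenic values lay above all wild-type values in 11.97% of genes and below them in 10.7%, where chance gives 10% each way. The closest to the threshold was Mrpl3, a protein of the mitochondrial ribosome, at 38.3 ± 3.70 CPM in wild-type and 19.9 ± 1.06 CPM in transgenic corneas (log2 fold change -0.94 ± 0.12, adjusted p = 0.127). Ptpn6, a tyrosine phosphatase of blood cells and epithelia, went from 44.9 ± 1.03 to 27.1 ± 2.65 CPM (-0.73 ± 0.11, adjusted p = 0.250), and Ifitm3, an interferon-induced membrane protein, from 164 ± 17.3 to 110.0 ± 0.304 CPM (-0.58 ± 0.11, adjusted p = 0.404).

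The other 7 of the 10 genes of smallest p, counted among those with a gene symbol and a mean of at least 1 CPM, were higher in transgenic corneas, none of them past the threshold. Among genes known only by an identifier, RGD1565462 had 3.11 ± 1.88 and 0.211 ± 0.0285 CPM and RGD1560730 4.52 ± 0.588 and 1.57 ± 0.458 CPM, lower in transgenic corneas and with p-values in the same range. Casp14, a protease of cornified epithelium, had 2.02 ± 0.449 CPM in wild-type and 6.01 ± 0.865 CPM in transgenic corneas (log2 fold change 1.57 ± 0.27). Ppp1r1b had 2.03 ± 0.750 and 6.25 ± 1.09 CPM. The nuclear envelope gene Syne3 had 9.67 ± 1.44 and 18.6 ± 2.35 CPM (0.95 ± 0.17), and B3glct, a glycosyltransferase, 8.07 ± 1.36 and 15.4 ± 1.18 CPM (0.93 ± 0.17). Log2 fold changes were 0.67 ± 0.11 for Cpxm2, 0.50 ± 0.09 for the fibrillar collagen gene Col5a1 and 0.51 ± 0.10 for Nrp2, a receptor for semaphorins and vascular growth factors. Adjusted p-values of the 7 genes with symbols lay between 0.380 and 0.404. DESeq2 called 57 genes (39 rose and 18 fell), among them all 10 of these genes of smallest p, while limma voom called NR3C2 alone. Leaving out wild-type cornea 1, 2 or 3 gave 6, 4 or 2 genes, and leaving out transgenic cornea 1 or 2 gave 36 or 5, with NR3C2 called each time.

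Genes of the corneal stroma were higher in transgenic corneas as a group. The keratocyte and stromal matrix list, named for the cells that build the collagen stroma, had 24 of 27 tested members higher, with a median log2 fold change of 0.37 (camera adjusted p = 6.8e-12). With an estimated correlation the list did not pass (camera adjusted p = 0.0988), and neither did it by fry (adjusted p = 0.0898). No member passed over all genes tested, while adjusted over the list alone 7 rose, 0 fell and 20 did not pass. The 7 were Col5a1, Bgn, Fmod, Prelp, Col12a1, Fbln1 and Pcolce. Bgn and Fmod, proteoglycans that bind collagen, had 325 ± 24.5 and 326 ± 27.9 CPM in wild-type and 472 ± 43.8 and 468 ± 42.9 CPM in transgenic corneas. Col5a1, which sets fibril width, had 67.0 ± 1.32 and 94.8 ± 3.03 CPM. Among other stromal proteoglycans the log2 fold change was 0.29 ± 0.11 for Kera, 0.07 ± 0.10 for Dcn and -0.01 ± 0.18 for Lum. Without transgenic cornea 2 none of the 7 passed over the list alone (0.0556 for Col5a1, Bgn and Fmod), and without wild-type cornea 1, 2 or 3 or transgenic cornea 1 the number was 6, 7, 5 or 6.

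The fibrosis and myofibroblast list had 23 of 26 tested members higher, with a median log2 fold change of 0.30 (camera adjusted p = 1.14e-07; adjusted p = 0.0988 with an estimated correlation). Adjusted over the list alone 3 rose (Ltbp2, Thbs1 and Fn1), 0 fell and 23 did not pass; none passed over all genes. Ltbp2, a matrix protein that binds microfibrils, had 25.8 ± 6.57 CPM in wild-type and 49.4 ± 5.81 CPM in transgenic corneas. Thbs1, a matricellular glycoprotein, had 389.6 ± 50.2 and 537 ± 34.8 CPM, and fibronectin (Fn1) 427 ± 41.5 and 562 ± 11.2 CPM. The 3 genes are matrix proteins, and Acta2, the smooth muscle actin of myofibroblasts, had a log2 fold change of 0.18 ± 0.12. Tgfb1 had -0.16 ± 0.14 and Ccn2 0.01 ± 0.24. None of the 3 passed over the list alone with each library left out in turn; the number was 1, 0 or 2 without wild-type cornea 1, 2 or 3 and 0 or 1 without transgenic cornea 1 or 2. Pigment-cell markers were also higher in both transgenic corneas: the pigment score was 1.17 and 2.03 there and 0.47, -0.76 and 0.28 in wild-type corneas 1 to 3.

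The corneal endothelium list, for the monolayer that pumps water out of the stroma, had 16 of 20 tested members higher, with a median log2 fold change of 0.14 (camera adjusted p = 2.2e-04; adjusted p = 0.141 with an estimated correlation). Adjusted over the list alone 3 rose, Slc4a4 and Col8a2 among them, 0 fell and 17 did not pass; none passed over all genes. The bicarbonate transporter gene Slc4a4 had 14.7 ± 3.63 CPM in wild-type and 28.1 ± 7.57 CPM in transgenic corneas, and Col8a2, a collagen of Descemet's membrane, 244 ± 22.3 and 313 ± 9.55 CPM. Slc4a11 and Aqp1, also abundant in this layer, had log2 fold changes of -0.08 ± 0.10 and 0.15 ± 0.10. Of the 3 members, 1 passed over the list alone without transgenic cornea 1, 3 without wild-type cornea 3 and 0 without any other library; without transgenic cornea 1 the list's adjusted p was 0.0499. The pigment score was also higher in transgenic corneas 1 and 2 (1.17 and 2.03, at most 0.47 in wild-type ones). Between these 2 corneas the list went the other way, with scores of 0.31 and 0.20. In wild-type corneas 1 to 3 list scores of 0.04, -0.05 and 0.01 had the same order as the pigment scores. With the pigment score as a covariate, chosen after seeing the data, the list was still called (camera adjusted p = 8.8e-04). Because the fit uses the preset correlation and the score is higher in both transgenic corneas, it cannot separate genotype from what the score measures.

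**Figure D2:**
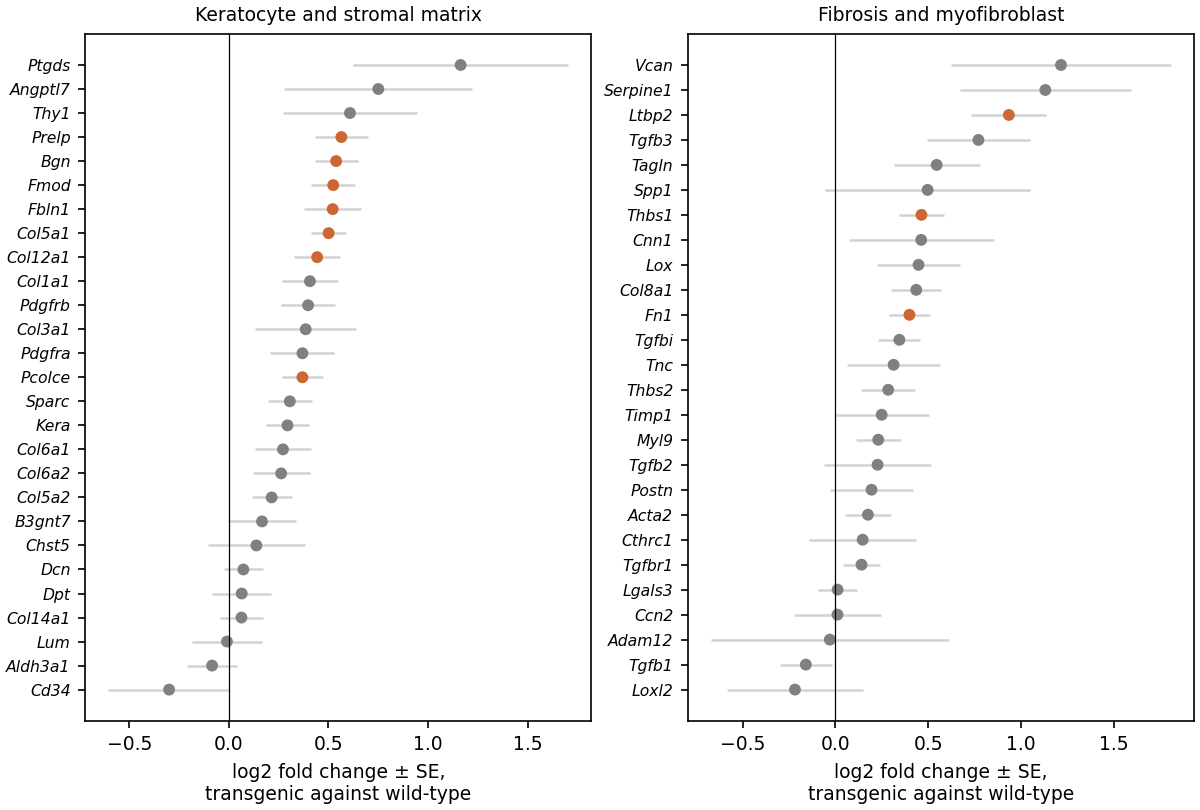
Log2 fold changes (horizontal axes, transgenic against wild-type, edgeR) with bars of 1 standard error for the tested members of the keratocyte and stromal matrix list (left) and the fibrosis and myofibroblast list (right); orange points passed adjusted over the list alone. On the left 24 of 27 points lie above 0, and on the right 23 of 26.

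Among tissues next to the cornea, markers of iris and retina were higher in transgenic corneas and lens markers lower. The iris, ciliary body and melanocyte list had 17 of 20 tested members higher in transgenic corneas, with a median log2 fold change of 0.95 (camera adjusted p = 6.8e-12; adjusted p = 0.327 with an estimated correlation). Adjusted over the list alone 9 rose, 0 fell and 11 did not pass; none passed over all genes. Trpm1 had 6.09 ± 2.13 and 15.1 ± 3.71 CPM, the pigment enzyme gene Tyr 1.85 ± 1.13 and 7.45 ± 3.61 CPM, and Best2, a channel of the ciliary epithelium, 0.127 ± 0.0315 and 1.09 ± 0.147 CPM. Myoc, which the trabecular meshwork and corneal stroma also express, had 194 ± 36.8 and 381 ± 138 CPM, with a log2 fold change of 0.97 ± 0.26, or 0.55 without transgenic cornea 2. Of the 9 members that rose, Best2 and Cpxm2 passed over the list alone with each library left out; the number was 9, 7 or 5 without wild-type cornea 1, 2 or 3 and 8 or 2 without transgenic cornea 1 or 2. The abundant pigment genes Tyrp1 and Pmel had 14.1 ± 10.2 and 9.04 ± 6.38 CPM in wild-type and 60.9 ± 26.9 and 36.1 ± 15.5 CPM in transgenic corneas, and neither passed over the list alone. In wild-type corneas 13 of the 20 members had a mean of at least 1 CPM, and Sox10 and Cnn1 are also in other lists.

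The retina and pigment epithelium list had 12 of 13 tested members higher, with a median log2 fold change of 0.65 (camera adjusted p = 9.7e-06; adjusted p = 0.419 with an estimated correlation). Over all genes and adjusted over the list alone, 0 rose and 0 fell. The visual cycle genes Rlbp1 and Rgr had 1.35 ± 0.840 and 0.430 ± 0.391 CPM in wild-type and 3.92 ± 0.359 and 2.49 ± 1.39 CPM in transgenic corneas. The retina score of wild-type cornea 1 (0.60) was close to that of transgenic cornea 1 (0.63), and the group difference of 0.71 had a 95% interval of -0.64 to 2.06. Lens genes went the other way: 12 of 13 were lower, with a median log2 fold change of -2.58 (camera adjusted p = 2.2e-04; adjusted p = 0.421 with an estimated correlation), and 0 rose and 0 fell over all genes or adjusted over the list alone. The crystallins Crygs and Cryba2 had 7.04 and 8.81 CPM in wild-type cornea 1, 1.96 and 2.64 CPM in cornea 2 and 1.27 and 1.41 CPM in cornea 3, against 0.655 CPM or less in both transgenic corneas. Wild-type cornea 1 had a lens score of 1.01, against -0.40 and -0.61 in the other wild-type corneas.

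**Figure D3:**
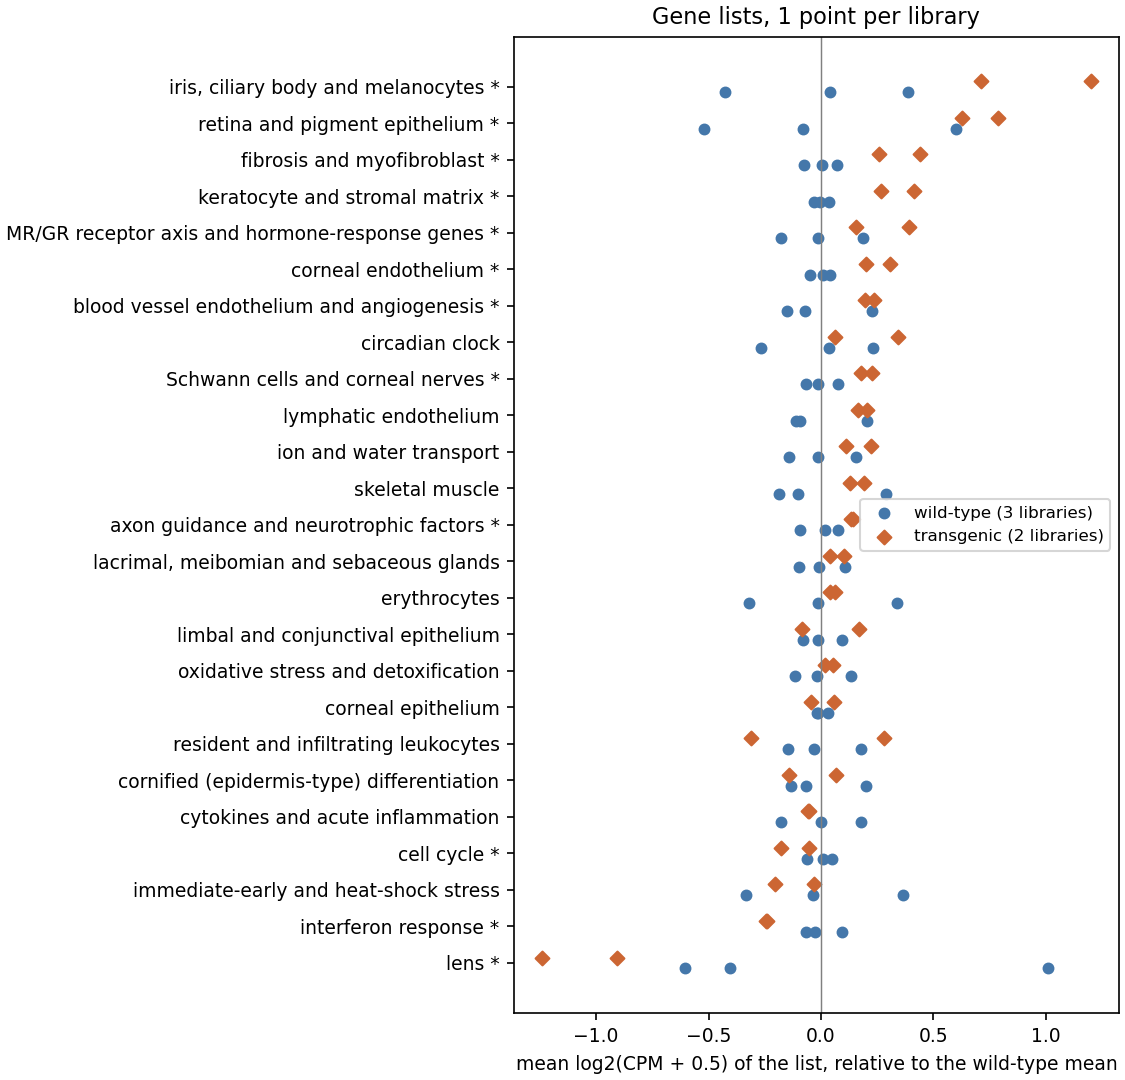
Scores of the 25 gene lists in each library (horizontal axis, mean log2(CPM + 0.5) of the members as a deviation from the wild-type mean; blue circles wild-type, orange diamonds transgenic); an asterisk marks the 12 lists with a camera adjusted p under 0.05. Both transgenic libraries lie above the wild-type ones for the stromal list (0.27 and 0.41), and wild-type cornea 1 has the highest lens score (1.01).

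Genes of the receptor axis and hormone response were modestly higher as a list. Of 26 tested members 19 were higher in transgenic corneas, with a median log2 fold change of 0.22 (camera adjusted p = 0.00894; adjusted p = 0.350 with an estimated correlation). No member passed, over all genes or adjusted over the list alone (0 rose and 0 fell). Atp1b1, a subunit of the sodium pump, had 64.3, 63.4 and 88.3 CPM in wild-type corneas 1 to 3 and 96.4 and 134 CPM in transgenic corneas 1 and 2, and Usp2, a deubiquitinase, 1.11 ± 0.306 CPM in wild-type and 1.47 and 3.25 CPM in transgenic corneas 1 and 2. Sgk1, the kinase through which aldosterone acts on sodium transport, had 83.7 ± 5.93 and 90.6 ± 3.06 CPM (log2 fold change 0.11 ± 0.10). Log2 fold changes were 0.22 ± 0.21 for the sodium channel gene Scnn1a, 0.62 ± 0.46 for Tsc22d3, 0.28 ± 0.32 for Fkbp5 and 0.04 ± 0.10 for the glucocorticoid receptor gene Nr3c1.

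Clock genes, several of which respond to steroids, varied between libraries within each genotype. The clock score was -1.28, 0.17 and 1.11 in wild-type corneas 1 to 3 and 0.73 and 1.73 in transgenic corneas 1 and 2, and the hormone-response scores without clock genes in the same order were -0.14, -0.05 and 0.18, then 0.16 and 0.36. The clock list had 12 of 18 members higher and was not called (camera adjusted p = 0.125), but it was called higher without wild-type cornea 3 (0.00876) or transgenic cornea 1 (0.0303), with 0 members passing over all genes or adjusted over the list alone. Cry1 had 12.6 ± 3.13 and 7.30 ± 0.568 CPM, and Rora 12.3 ± 1.04 and 15.5 ± 0.915 CPM. The hormone-response list did not pass without wild-type cornea 1 (camera adjusted p = 0.0876) or without transgenic cornea 2 (0.0559). It did not pass either with the clock score as a covariate (0.398) or with the pigment score (0.392), both chosen after seeing the data.

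Vessel and nerve lists were called higher in transgenic corneas, beside the pigment-cell markers described above. The blood vessel list had 26 of 32 members higher (median log2 fold change 0.29, camera adjusted p = 7.7e-04; adjusted p = 0.419 with an estimated correlation), with 0 passing over all genes or adjusted over the list alone. Its scores overlapped between genotypes: 0.23, -0.07 and -0.15 in wild-type corneas 1 to 3 and 0.20 and 0.24 in transgenic corneas 1 and 2. Kdr, a receptor for vascular endothelial growth factor, had 10.4 ± 1.84 and 16.2 ± 1.64 CPM, and Angpt1, which stabilizes vessels, 3.35 ± 0.366 CPM in wild-type and 4.59 and 8.63 CPM in transgenic corneas 1 and 2. The Schwann cell and nerve list had 14 of 22 higher (median 0.22, camera adjusted p = 0.00310; adjusted p = 0.350 with an estimated correlation). Adjusted over the list alone Ncam1 and S100b rose, 0 fell and 20 did not pass; Ncam1, an adhesion molecule, had 55.4 ± 5.35 and 73.2 ± 1.36 CPM, and S100b, a calcium-binding protein of glia, had a log2 fold change of 0.77 ± 0.21, or 0.46 without transgenic cornea 2. The axon guidance list had 17 of 28 higher (median 0.17, camera adjusted p = 0.0150; adjusted p = 0.327 with an estimated correlation), and adjusted over the list alone 4 rose (Nrp2, Ntn1, Ntrk2 and Sema3d) and 0 fell. The guidance cue Ntn1 had 31.0 ± 1.07 and 42.8 ± 6.15 CPM, and Sema3d a log2 fold change of 1.19 ± 0.34, or 0.50 without transgenic cornea 2. None of the members that rose in the nerve and axon guidance lists passed over the list alone with each library left out.

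No member of these 3 lists passed over all genes. The blood vessel list did not pass without wild-type cornea 3 (camera adjusted p = 0.103) or with the replicate number as a block (0.0905), the nerve list without transgenic cornea 1 (0.0564) and the axon guidance list without wild-type cornea 2 (0.0864) or transgenic cornea 1 (0.0910). With the pigment score as a covariate, chosen after seeing the data, none of the 3 passed (0.825, 0.302 and 0.709). The lymphatic list, with 8 of 11 members higher, was not called (camera adjusted p = 0.0900), but it was called higher without wild-type cornea 1 (0.0256) or transgenic cornea 2 (0.0284); adjusted over the list alone Nrp2 rose and Ccl21 fell. Ccl21, a chemokine of lymphatic vessels, had 4.44 ± 2.07 and 1.34 ± 0.263 CPM.

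Interferon-response genes were lower in transgenic corneas: 22 of 28 tested members, with a median log2 fold change of -0.20 (camera adjusted p = 1.5e-04; adjusted p = 0.141 with an estimated correlation). No member passed over all genes or adjusted over the list alone (0 rose and 0 fell). The antiviral gene Ifit2 had 163 ± 42.0 CPM in wild-type and 90.4 ± 6.78 CPM in transgenic corneas, its relative Ifit3 68.4 ± 19.5 and 36.9 ± 6.39 CPM, and the peptide transporter gene Tap1 37.7 ± 4.91 and 28.5 ± 2.94 CPM. Irf1 had a log2 fold change of 0.04 ± 0.14. Cell cycle genes were lower in 30 of 33 cases by a small amount, with a median of -0.11 (camera adjusted p = 1.5e-04; adjusted p = 0.419 with an estimated correlation), and 0 passed over all genes or adjusted over the list alone. Ube2c had 32.9 ± 3.12 and 25.4 ± 0.364 CPM, and Cdk1, the kinase of mitosis, 27.1 ± 2.84 and 21.6 ± 2.41 CPM. The pigment score also differed between the groups, at 1.17 and 2.03 in transgenic corneas and at most 0.47 in wild-type ones. With that score as a covariate, chosen after seeing the data, the interferon (camera adjusted p = 8.8e-04) and cell cycle lists (0.0253) were still called lower. That fit uses the preset correlation and a score that is higher in both transgenic corneas. It therefore cannot separate genotype from what the pigment score measures. The cell cycle list did not pass without transgenic cornea 2 (camera adjusted p = 0.157), and its scores overlapped (-0.06 in wild-type cornea 2 and -0.05 in transgenic cornea 1).

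Leukocyte genes separated the transgenic corneas from each other. The list had 17 of 29 tested members higher and was not called (camera adjusted p = 0.852), with 0 passing over all genes or adjusted over the list alone; its score was -0.31 in transgenic cornea 1 and 0.28 in cornea 2. Without transgenic cornea 1 the list lay higher in the transgenic group (camera adjusted p = 0.0205), and without transgenic cornea 2 it lay lower (2.0e-04). The class II genes RT1-Ba and RT1-Db1, which present antigen, had 6.29 ± 1.19 and 5.59 ± 0.992 CPM in wild-type and 3.17 ± 1.59 and 2.59 ± 1.70 CPM in transgenic corneas. In transgenic corneas 1 and 2 RT1-Ba had 2.04 and 4.30 CPM and RT1-Db1 1.39 and 3.79 CPM, so cornea 1 was the lower for both. The list's median log2 fold change (0.14) and mean (0.02) were above 0 while camera ranked it lower than other genes.

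Epithelial genes differed little. The corneal epithelium list had 14 of 25 members higher, with a median log2 fold change of 0.02, and was not called (camera adjusted p = 0.754); Krt12 had -0.06 ± 0.16, Krt5 0.07 ± 0.13 and Pax6 -0.07 ± 0.10. Epcam, an adhesion protein, had 189.8 ± 15.8 and 149.6 ± 8.41 CPM, and the secreted chaperone Clu 70.5 ± 17.4 and 113 ± 14.3 CPM, with 0 members passing over all genes or adjusted over the list alone. The limbal and conjunctival list (median 0.05, camera adjusted p = 0.991) held Ifitm3, which fell adjusted over the list alone, and Krt18, at 3.61 ± 0.444 and 5.54 ± 1.62 CPM. The cornified list (median -0.06, camera adjusted p = 0.688) held Casp14, which rose adjusted over the list alone, and Tgm3, at 3.18 ± 0.812 and 2.02 ± 0.248 CPM. For the corneal and limbal lists camera pointed down while the median and mean were above 0.

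The remaining lists were not called with all libraries, and none of their members passed over all genes or adjusted over the list alone. Ion and water transport (median 0.12, camera adjusted p = 0.0750) was led by Atp1b2, at 26.7 ± 1.96 and 36.9 ± 3.60 CPM, and Atp1b1; it was called higher without wild-type cornea 1 (0.0186). Cytokines and acute inflammation (-0.10, 0.342) held Vcam1, an adhesion molecule, at 10.5 ± 2.37 and 17.0 ± 0.612 CPM, and Mmp9 at 1.00 ± 0.890 and 0.211 ± 0.0285 CPM, and were called lower without wild-type cornea 3 (0.0181). Immediate-early and heat-shock genes (-0.15, 0.216) held Hsp90aa1 at 176 ± 15.8 and 138 ± 6.99 CPM and Hspb1 at 282 ± 20.4 and 330.2 ± 29.9 CPM, and were called lower without wild-type cornea 3 (0.00169) or transgenic cornea 1 (0.0303). Oxidative stress genes (0.04, 0.309) held Sod3, the extracellular superoxide dismutase, with a log2 fold change of 0.65 ± 0.16 and Aldh1a1, an aldehyde dehydrogenase, with 0.26 ± 0.11.

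Genes of skeletal muscle (median 0.12, camera adjusted p = 0.224) had Ryr1 at 37.7 ± 3.20 CPM in wild-type and 34.4 and 22.8 CPM in transgenic corneas 1 and 2, and Tnnt3 at 7.31 ± 2.15 CPM and 9.25 and 13.0 CPM. They were called higher without wild-type cornea 1 (0.00312). Gland genes (0.12, 0.617) had Plin2 with a log2 fold change of 0.40 ± 0.23 and Scd at 97.0 ± 7.48 and 107 ± 35.0 CPM. Erythrocyte genes (0.13, 0.925), whose mean was -0.06 and which camera ranked lower, had Tfrc at 21.7 ± 4.33 and 17.6 ± 3.86 CPM and Klf1 at 1.07 ± 0.520 and 0.621 ± 0.158 CPM. Of the 25 lists, camera called 12 (9 higher and 3 lower) with the preset correlation, 0 with an estimated correlation and 0 by fry. Other splits of the libraries into 3 and 2, which mix or reverse the genotypes, called from 1 to 12 lists at the preset correlation. Of the 32 calls adjusted over the list alone, 5 passed with each library left out in turn: Casp14, Ifitm3, Best2, Cpxm2 and, in the lymphatic list, Nrp2. Without wild-type cornea 1, 2 or 3 the number was 22, 18 or 22, and without transgenic cornea 1 or 2 it was 21 or 7.

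At the level of isoforms, single transcripts of Dennd1a and Gtf2ird2 were read in wild-type corneas and at 0 in transgenic ones, and transcripts of the transgene the other way round. None passed: the edgeR test called 0 of 27110 isoforms, of which 1080 had an unadjusted p under 0.05; limma voom called 0 and DESeq2 284 (113 rose and 171 fell). Among named genes, an isoform of Dennd1a (ENSRNOT00000025443) had 7.74 ± 1.15 CPM in wild-type corneas and 0 in both transgenic corneas (adjusted p = 0.575), while the whole gene had 20.2 ± 3.30 and 22.6 ± 1.12 CPM. An isoform of Gtf2ird2 (ENSRNOT00000002030) had 2.39 ± 0.300 and 0 CPM, against 6.24 ± 0.288 and 6.72 ± 0.315 CPM for the gene. Isoforms at 0 in one group and over 2 CPM in the other numbered 143. Of the 10 splits of the libraries into 3 and 2, 3 reached that number, the real one among them, and the highest other had 149. The Mrpl3 isoform ENSRNOT00000017280 carried the difference of its gene, at 35.3 ± 3.06 and 18.5 ± 0.840 CPM (log2 fold change -0.93 ± 0.12, adjusted p = 0.947). Human NR3C2 counts were assigned mostly to ENST00000511528 (21.6 ± 2.22 CPM, adjusted p = 0.575) and ENST00000342437 (10.5 ± 0.842 CPM, adjusted p = 0.896), at 0 in all wild-type libraries. In the simulation the isoform test recovered 29 of 50 isoforms changed 8-fold.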

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

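Genes from isoform sums, thinned libraries and the clock and pigment covariates were chosen only after the results were seen; the other alternatives were fixed before the data were examined. The count of called genes, 1 in the fit reported, was 1 with RLE size factors, limma voom, a minimum fold change of 1.5 and thinned libraries. It was 2 with no filter (Mrpl3 added, adjusted p = 0.0142), 2 with genes added from isoform sums (LOC100912163 added and named after its values were seen, at 0 in wild-type and 6.18 ± 0.375 CPM in transgenic corneas), and 57 with DESeq2; the cause of these differences was not tested. It was 0 with the stricter filter, which drops NR3C2 because only 2 libraries express it. It ran from 2 to 36 with a library left out, where a lone transgenic library is assumed to vary like the wild-type ones. Isoform calls were 0 except for 284 with DESeq2. List calls were 12 with RLE, no filter, F ranking, added genes and thinned libraries, and 14 with the stricter filter. They were 16 with the clock covariate and 8 with the pigment covariate. The pigment score is made of members of the iris list and the clock score of members of the clock list. The iris list's lost call with pigment (camera adjusted p = 0.804) and the clock list's turn with clock (0.126) were thus largely built in. List calls were 0 with an estimated correlation and 0 by fry. Both of the last tests allow for correlation among members. In the keratocyte, fibrosis, corneal endothelium, interferon and axon guidance lists this does not account for the lost calls. The estimates there were 0.0129, -0.0108, -0.0025, -1.8e-04 and 0.0121, beside the preset 0.01. Some lists had more, up to 0.630 for retina genes. Camera also takes its degrees of freedom from the few libraries when it estimates the correlation, and from the genes when it is preset. Calls can therefore be lost without any correlation. How much each contributed was not tested, and neither was the cause of the calls lost by fry.

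With the replicate number as a replicate block, 16 genes (8 rose and 8 fell) and 14 lists were called. The labels tie these numbers to no shared litter or day. Deviations from the group means correlated across genes at -9.0e-04 for number 1 and -0.116 for number 2. With 2 transgenic corneas the deviations of one mirror those of the other, so these values can neither show nor exclude a shared litter or day.

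Over the 55 named genes, direction and side of the threshold stayed the same in 743 comparisons with an alternative, 19 gained a call, 15 of them with DESeq2, and Scd turned, with log2 fold changes from -0.24 to 0.44 with a library left out. Of the 55 named genes only NR3C2 was called in the fit reported, so staying the same mostly means not called in both fits. Most were also picked by p-values of these same data. Over the lists, 310 comparisons stayed the same, 157 of these without a call either way. A further 38 lost a call, 20 gained one and 31 turned, 27 of the turned ones without a call either way. Besides those with a library left out, calls were gained by lymphatic (0.0288) and clock genes (0.0487) with the stricter filter, by clock (2.6e-05), immediate-early (1.0e-04) and cytokine genes (0.0184) with the block, by lymphatic (0.0179), muscle (6.2e-04), ion transport (0.0112) and oxidative stress genes (0.0231) with the clock covariate and by leukocytes with the pigment covariate (2.6e-07). Turned lists with a call in either fit, by adjusted p, were immediate-early genes with the clock covariate (0.00534), leukocytes without transgenic cornea 1 (0.0205), and corneal epithelium (0.0253) and retina (0.678) with the pigment covariate. Leukocytes also turned with fry (0.952) and ran from 2.0e-04 to 0.823 with a library left out. Without a call, limbal genes turned with no filter (0.875), the stricter filter (0.939) and the block (0.668); erythrocytes with no filter (0.5003), fry (0.952), added genes (0.808) and the clock covariate (0.472); cornified genes with the F ranking (0.992), the clock (0.143) and the pigment covariate (0.836); muscle with no filter (0.821) and pigment (0.882); cytokines (0.472) and clock genes (0.126) with the clock; oxidative stress (0.524) and ion transport (0.875) with pigment. With a library left out, adjusted p ran from 0.131 to 0.891 for limbal genes, 0.481 to 0.968 for erythrocytes, 0.0770 to 0.933 for cornified genes, 0.0181 to 0.933 for cytokines, 0.00169 to 0.674 for immediate-early genes and 0.0740 to 0.794 for corneal epithelium; the cause was not tested. At the depth of these libraries, 29 of 50 simulated 8-fold changes were recovered for isoforms and 50 of 50 for genes; depth itself was not varied in the simulation.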

Other observations

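The tests on the pigment score, the epithelial share and the clock score were chosen only after the results were seen, as were the covariate fits and the thinned libraries; the counts over other splits were fixed before their results were seen.

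Limbal keratins differed between the transgenic corneas. Krt15 and Krt19, keratins of the limbal and conjunctival epithelium that the gene table lacks, were taken from isoform sums, which hold only the counts of isoforms that carry the gene's name. Krt15 had 200.4 CPM in transgenic cornea 1 and 600.1 CPM in cornea 2, against 400.1 ± 31.2 CPM in wild-type corneas, and Krt19 had 7.86 and 29.8 CPM against 19.1 ± 0.980 CPM. Krt13 had 1986 and 3949 CPM in the transgenic corneas against 2340 ± 644 CPM. The complement genes C1qa and C1qc had 1.81 and 1.66 CPM in transgenic cornea 1 and 5.16 and 5.73 CPM in cornea 2, and Cd74 had 12.8 and 27.6 CPM.

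Further genes of the 30 with the smallest p were chosen after their values were seen, and none passed. Fstl1, a secreted glycoprotein of stromal cells, had 71.0 ± 3.76 CPM in wild-type and 95.5 ± 0.590 CPM in transgenic corneas (edgeR log2 fold change 0.43 ± 0.09). The collagen receptor gene Ddr2 had 21.5 ± 3.22 and 33.4 ± 1.66 CPM (0.63 ± 0.14), and Igfbp3, which binds insulin-like growth factors, 7.55 ± 1.11 and 15.9 ± 5.13 CPM (1.08 ± 0.22). Among the 3 nearest tested genes on each side of Mrpl3 in the gene order of assembly GRCr8, log2 fold changes were 0.80 ± 0.50 for Ackr4, 0.02 ± 0.09 for Dnajc13 and -0.52 ± 1.46 for Cpne4 on one side and -0.01 ± 0.16 for Nudt16, -0.45 ± 0.40 for Nek11 and -0.18 ± 0.17 for Aste1 on the other, beside -0.94 ± 0.12 for Mrpl3 itself.

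Stromal and fibrosis lists were higher in both transgenic corneas (score difference 0.34 on the log2 scale, 95% interval 0.12 to 0.57). The keratocyte median was 0.353 after thinning all libraries to the smallest total, from 0.369. Thinning leaves the expected CPM as it was, and all 27 tested members had a wild-type mean of at least 1 CPM. The median could therefore hardly move, and thinning cannot decide on library size. Library totals overlapped, at 26280687 counts in transgenic cornea 1 and 27692181 in wild-type cornea 1. A smaller share of epithelium would raise all stromal genes alike and stays open. The 13 keratocyte members at 100 CPM or more ran from -0.01 for Lum to 0.75 for Angptl7. Their heterogeneity p was 0.107 by random draws of t-distributed errors (n = 13 genes, not independent). That reference was chosen after treating the errors as known had given 0.0104. Such a share would also lower epithelial genes, by an amount that depends on the share, which was not measured. The corneal epithelium score was 0.06 and -0.04 in transgenic corneas 1 and 2 and -0.01, 0.03 and -0.02 in wild-type corneas 1 to 3. Tissue of the iris, ciliary body and pigment epithelium carried over at dissection may contribute: within groups the stromal score changed by 0.0985 per unit of pigment score (95% interval -0.117 to 0.314), an interval that holds both 0 and the 0.215 that the group difference needs. With the pigment score as a covariate the keratocyte (adjusted p = 2.7e-06) and fibrosis lists (0.0253) still passed camera at the preset correlation. Without the covariate neither passed camera with an estimated correlation (0.0988 for each). The score difference at equal pigment score was 0.19 (95% interval -0.22 to 0.60). Genotype, epithelial share and carried-over tissue cannot be told apart with 5 corneas whose pigment score is higher in both transgenic ones, and an effect of the receptor on stromal matrix stays open as a hypothesis.

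The hormone-response list was higher in transgenic corneas, and time of day at collection may account for it, since its score without clock genes changed with the clock score within groups by 0.138 per unit (95% interval -0.0179 to 0.295). At equal clock score the groups differed by 0.0879 (95% interval -0.238 to 0.414), against 0.258 (95% interval -0.198 to 0.714) without that adjustment. All 3 intervals hold 0, so clock phase and genotype cannot be told apart, and clock genes that respond to the receptor itself would give the same values.

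Pigment genes were higher in transgenic corneas, by 1.601 in the pigment score (95% interval -0.27 to 3.48), and wild-type corneas differed among themselves by 1.23. Pieces of iris, ciliary body or pigment epithelium in varying amounts could give such a spread: within groups the retina and pigment epithelium score changed by 0.578 per unit of pigment score (95% interval -0.728 to 1.88), which leaves this open with 5 libraries. The iris, ciliary body and melanocyte list was still called with thinned libraries (camera adjusted p = 1.4e-12) and with the clock score as a covariate (3.2e-12), but not with an estimated correlation (0.327). Since thinning leaves the expected CPM as it was, the call on thinned libraries cannot decide on library size. No other technical explanation was given a test of its own. A difference by genotype stays open, since it cannot be told apart from such pieces of tissue here.

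The 5 libraries can be split into 3 and 2 in 10 ways, too few for a share under 0.05. For genes, 6 of the 10 splits called at least 1, the real count, and the highest other called 6; for lists, 2 splits called at least the real 12, and the highest other also called 12; for isoforms at 0 in one group and over 2 CPM in the other, 3 splits reached the real 143, and the highest other had 149. Of the other splits, that of wild-type cornea 3 with transgenic cornea 2, which have the highest clock scores, called 6 genes, and that of wild-type corneas 1 and 2 gave 1747 genes at an unadjusted p under 0.05 against 841 for the real one. The simulation with no gene changed called 5 genes.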
